A study of Oryza sativa with 16 samples.

How the data were processed

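Leaf RNA of 4 groups of rice, an aromatic and a non-aromatic bulk of 6 inbred lines each and the parents Pusa 1121 and Pusa 1342, was hybridised to 16 Affymetrix rice arrays, 4 per group. RNA was extracted with a Qiagen kit and labelled with biotin, per the labels' protocols. The submitters' processing notes name GCOS 1.2 and RMA, with no role or order; any further settings and the genome build are not given in the sources used here. The deposited data hold 1 intensity per probe set and array, on a linear scale from 0.201 to 45123, although RMA usually returns log2 values. That the values are linear and were made equal in distribution between arrays by the authors was read from the table, in which the median (64.2) and upper quartile (434) are the same on every array. Because of this equal distribution, a shift of all genes in 1 group would not be seen. No detection calls were used, and low intensities were not treated as absence.

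Of 57381 probe sets, 187 controls were left out and 57194 were tested. Names came from the platform annotation, updated through NCBI gene identifiers with the gene table of assembly ASM3414082v1, which was used only for names, chromosome and gene order. In total 22436 probe sets had 1 gene, 95 had several and were not named, and 34663 had none listed here. These gave 17905 genes, all found in the gene table, 2457 of them with a published name. Each gene was read through the probe set with the highest mean over all arrays; 3444 genes had several, and other probe sets of named genes that did not pass or went the other way are noted beside the comparison concerned.

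Groups were taken from the sample labels. Values were transformed as log2(value + 1), so the size of a difference against dim values depends on the pseudocount, and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 group means in 1 fit). Residual degrees of freedom were 12. The median residual SD was 0.691 on the log2 scale, 1.09 in the dimmer and 0.196 in the brighter part of the probe sets, so small differences were detectable mainly in bright genes. Tested contrasts were the aromatic minus the non-aromatic bulk, the same for the parents, the parental minus the bulk difference, and the mean of the bulks minus that of the parents. All tests were two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Median log2 differences over all probe sets lay between -0.0247 and 0.0162. The equal distribution of the arrays keeps these small, so they cannot show whether a general shift occurred. No correction for such a shift was made.

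Gene lists were tested with camera in limma at a preset correlation of 0.01, on 1 probe set per gene, for lists with at least 5 measured genes and with adjustment over the 16 lists; the correlation was also estimated, and fry was run. The lists cover scent, amine and proline genes, alcohol and aldehyde, oxylipin, terpene, phenylpropanoid, cytochrome P450, photosynthesis, defence, WRKY, heat shock, clock and flowering, and resistance genes, and markers of floral or meristem tissue, seed, root, senescence and ribosomes. They were fixed before the data were examined, but had to be rewritten as gene symbols afterwards and before any comparison, since the gene table holds no descriptions. A further 7 lists (JAZ, chlorophyll synthesis, water stress, phosphate, cell cycle, expansin and aquaporin genes) were added after the data were seen. Chromosomes and the 50 genes on either side of BADH2 were tested with Fisher's exact test, two-sided.

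Named genes followed a rule set before the data were examined. It takes fragrance and proline genes (BADH2, BADH1, P5CS1, P5CS2, OAT), the 8 largest rises and falls per main comparison among called genes whose groups did not overlap, the 10 largest shared differences, up to 4 members per list, and the 5 largest each way for the other contrasts. P5CR, PRODH and P5CDH, also in the rule, could not be matched to a name and were not analysed here. The same ranks among genes with a published name were added later, and the text names a part of the genes so chosen.

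The steps were tested on simulated data for both main comparisons over 57194 probe sets, with 67, 67 and 66 changed by 0.5, 1 and 2 log2 units. In the simulated bulks, 41.8% of changes of 0.5 log2, 62.7% of changes of 1 and 78.8% of changes of 2 were recovered, and 7 unchanged probe sets were called. In the simulated parents the shares were 40.3%, 59.7% and 78.8%, with 4 unchanged ones called. Far fewer probe sets were changed than passed in the real data, so the shares recovered need not hold there. The heat shock list, planted with every member shifted by 1 log2 unit and genes drawn independently, was called alone among 16 in each. Its medians in the real data were smaller, at -0.125 in the bulks and -0.439 in the parents. The chromosome test was run on calls drawn at random, not on the simulated arrays. There a planted chromosome was called, but 4 chromosomes were called in all in the bulks and 3 in the parents.

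Alternatives were quantile normalization, median centring, the brighter part of the probe sets, a replicate block, a trended prior, array weights, a 2-fold minimum, a pseudocount of 16, a fit of only the groups compared, other probe sets, other list tests, other neighbourhood sizes, and each replicate left out. Ranges of adjusted p over alternatives leave out fry and other probe sets, whose results are given separately. Data were handled with data.table (version 1.17.8), statmod 1.5.0 and pandas 2.3.3 and drawn with matplotlib 3.10.9.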

Results

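Leaf RNA was measured on the Affymetrix rice GeneChip in 16 samples of Oryza sativa, 8 from the aromatic rice Pusa 1121 and the non-aromatic rice Pusa 1342 and 8 from lines of a cross between them. Recombinant inbred lines, which are fixed by selfing and carry a mosaic of both parental genomes, had been scored by smell, and RNA of the extreme lines was combined. The aromatic bulk pooled 6 strongly scented lines and the non-aromatic bulk pooled 6 unscented lines. Each parent formed a further group, and every group held 4 arrays described by the submitters as biological replicates. Leaves were taken about 25 days after transplanting of field-grown, untreated plants. Every array had the same median intensity of 64.2. With 4 arrays per group, the median residual SD on the log2 scale was 1.09 in the dimmer and 0.196 in the brighter probe sets. Arrays of 1 group correlated more closely (mean r across probe sets from 0.917 to 0.930) than arrays of different groups (0.886 to 0.904). The labels do not say that the replicates came from separate plants or separate pools, so the p-values measure the spread between these arrays, which may be technical.

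BADH2 (LOC4345606, chromosome 8) encodes a betaine aldehyde dehydrogenase, and its loss of function is the known major source of rice fragrance. Its intensity was 370 ± 39.9 (SD, n = 4) in the aromatic bulk, 733 ± 59.5 in the non-aromatic bulk, 349 ± 54.2 in the aromatic parent and 2233 ± 10.3 in the non-aromatic parent (n = 4 each). It was lower in the aromatic group of both pairs, by a log2 difference of -0.99 between the bulks (SE 0.115, limma adjusted p = 3.23e-05) and -2.69 between the parents (adjusted p = 5.93e-10). The difference was larger in the parents by -1.70 (adjusted p = 4.24e-06). Its paralog BADH1 fell by 1.19 on the log2 scale in the aromatic parent (adjusted p = 2.33e-06), while the bulks, at 1005 ± 43.4 and 1144 ± 75, did not differ past the threshold (adjusted p = 0.336).

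Of the genes of proline synthesis, P5CS1 and OAT were lower in the aromatic parent. P5CS1, a pyrroline-carboxylate synthase, had 2397 ± 81.4 in the aromatic parent and 6537 ± 76.1 in the non-aromatic parent, a log2 difference of -1.45 (adjusted p = 6.86e-10). Between the bulks it went the other way, at 5087 ± 29.3 in the aromatic and 4259 ± 199 in the non-aromatic bulk (log2 0.26, adjusted p = 0.0103), a call that was lost when only these arrays entered the fit (adjusted p = 0.078; from 2.17e-05 to 0.078 over 17 alternatives). OAT, ornithine aminotransferase, fell by 0.89 in the aromatic parent (adjusted p = 5.27e-07) and had log2 -0.06 between the bulks (adjusted p = 0.669). P5CS2 had a log2 difference of -0.58 between the parents (adjusted p = 0.00864), but none of its 3 other probe sets passed, with 1.84, -0.21 and 0.05. It did not differ between the bulks (adjusted p = 0.993).

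**Figure D1:**
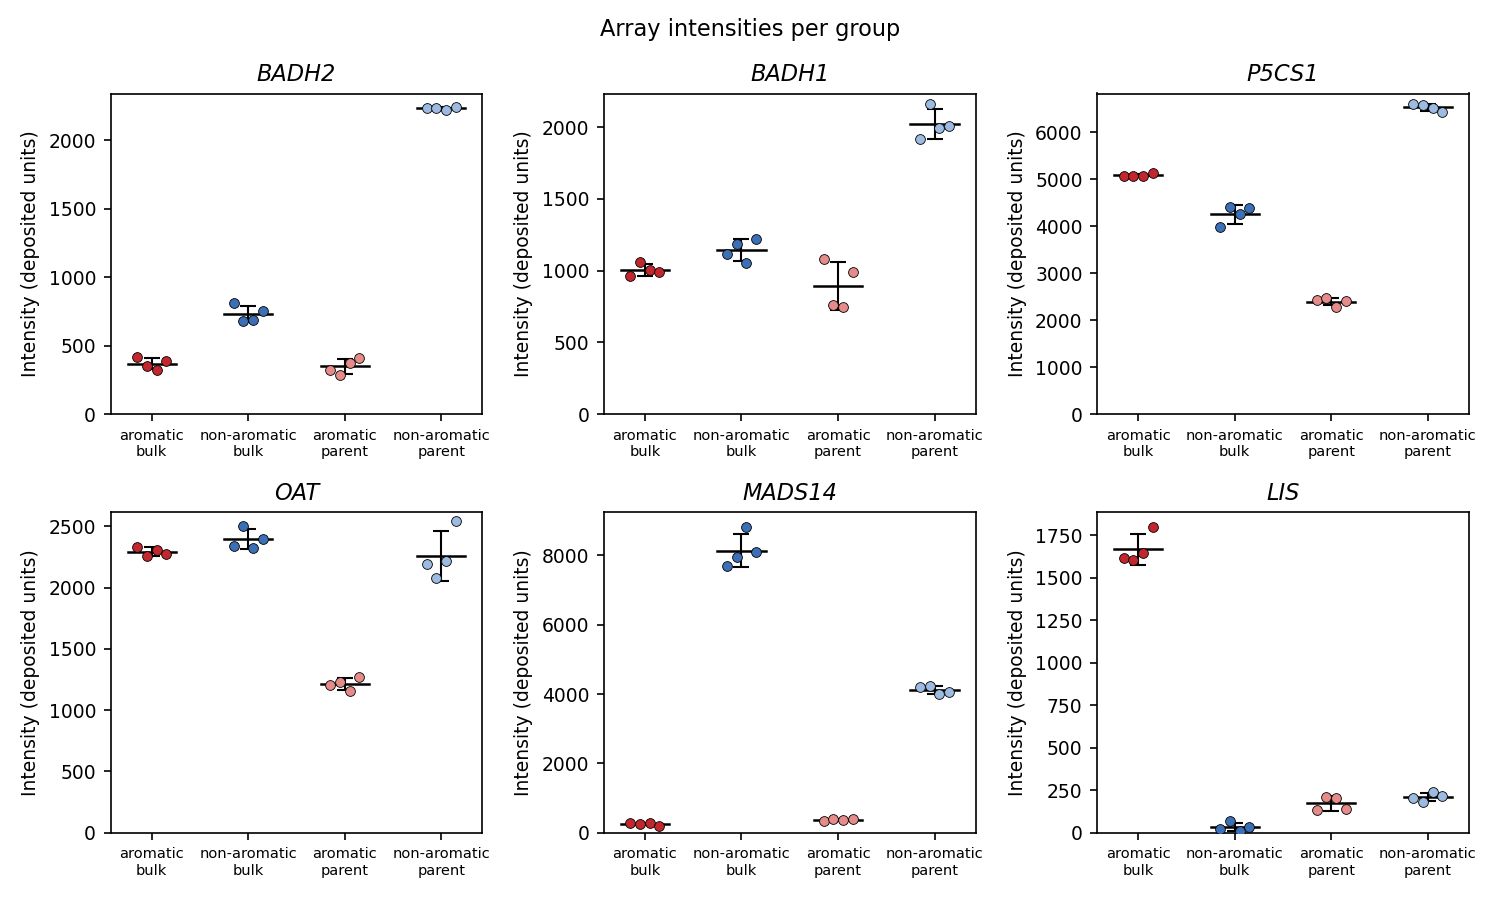
Intensity (linear deposited units, axis from 0) of BADH2, BADH1, P5CS1, OAT, MADS14 and LIS on each array, by group; points are the 4 arrays of a group, the long line is their mean and the bars are 1 SD. BADH2 averaged 370, 733, 349 and 2233 from left to right, and P5CS1 was lowest in the aromatic parent at 2397.

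The comparison of the bulks asked which leaf transcripts separate pooled scented lines from pooled unscented lines of the same cross. LIS, linalool synthase, had 1667 ± 88.8 in the aromatic bulk against 33.8 ± 25.1 in the non-aromatic bulk (n = 4 each, log2 5.87, adjusted p = 2.37e-07). BURP2 had 25800 ± 1039 against 474 ± 153 (log2 5.82). The unnamed loci LOC4334900 and LOC4326149 rose by 5.52 and 4.83, the cytokinin oxidase gene CKX3 by 4.43, the beta-tubulin gene OsTUB6 by 2.86 and the lipoxygenase gene LOX1.1 by 3.44. LOC9270995 had 340 ± 15.8 against 14.5 ± 19.0, with 1 non-aromatic array, replicate 4, at 43.0 and the others at or below 6.14. ADC1, arginine decarboxylase, rose by 0.69 (adjusted p = 1.36e-05), though its other probe set did not pass (log2 0.13) and 1 non-aromatic array lay apart at 12990, and the starch synthase gene SSI fell by 0.59.

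Among the genes that were lower in the aromatic bulk, MS and ICL encode malate synthase and isocitrate lyase, the enzymes of the glyoxylate cycle. MS had 16.8 ± 15 against 679 ± 119 (log2 -5.58, adjusted p = 1.92e-06), and ICL 42.6 ± 14.2 against 678 ± 91.3 (log2 -4.01, adjusted p = 6.66e-05). MADS14, a meristem identity gene of the flowering transition, had 252 ± 37.1 against 8141 ± 484 (log2 -5.02, adjusted p = 9.43e-12), and all 4 of its probe sets fell. MADS34 fell by 4.15, and the florigen gene Hd3a had 290 ± 18.7 against 1913 ± 49.4 (log2 -2.72). The flowering regulator MADS50 and the pseudo-response regulator PRR37 rose by 2.10 and 0.90; a further probe set of PRR37 did not pass (log2 0.15). The chitinase gene Cht5 fell by 3.95, the nicotianamine synthase gene NAS2 by 3.83, and the unnamed loci LOC4337008 and LOC4347994 had -6.80 and -5.34; a weak second probe set of LOC4347994 did not pass (log2 -0.55).

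In all, 10634 of 57194 probe sets passed an adjusted p under 0.05 in limma, 5430 of them higher and 5204 lower in the aromatic bulk. Of 17905 genes, each read through its brightest probe set, 2947 rose, 2922 fell and 12036 did not pass. Over all 17905 genes, called or not, 7404 had all 4 arrays of 1 bulk above all 4 of the other, an order that chance gives to 2.86% of genes. At least 2-fold differences were fewer, at 3417 probe sets.

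Heat shock genes were lower in the aromatic bulk. Of 45 measured members 18 fell, 3 rose and 24 did not pass, and 23 passed when adjusted over the list alone. HSP24.1, a small heat shock protein, had 991 ± 22.7 against 3430 ± 174, HSP18.6 had 603 ± 40.8 against 2159 ± 200, and HSP17.9A had 1468 ± 48.8 against 3429 ± 202. Another probe set of HSP18.6 went the other way without passing (log2 0.24). Limma's camera called this list alone among the 16 tested (adjusted p = 0.0215, and adjusted p = 0.0371 with an estimated correlation).

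The terpene list did not pass in the bulks (12 fell, 6 rose and 18 did not pass, with 21 adjusted over the list alone, adjusted p = 0.0883). It passed with probe sets averaged (adjusted p = 0.0419; up to 0.158 over 13 alternatives). The diterpene synthase genes CPS4 and CPS2 and the cytochrome P450 gene CYP99A3, all of phytoalexin synthesis, fell, with log2 differences of -2.79, -2.74 and -1.72. In defence, Cht-1 fell by 1.92 and 7 of 17 pathogenesis genes fell, 1 rose and 9 did not pass (8 adjusted over the list alone, adjusted p = 0.111). The pathogenesis list passed among the brighter probe sets (adjusted p = 0.0443; up to 0.176). The transcription factor gene WRKY76 fell by 1.56, and 4 of 6 WRKY genes fell with 2 not passing (5 adjusted over the list alone, adjusted p = 0.111). The senescence gene SGR fell by 1.18, with 2033 ± 250 against 4593 ± 340, in a list where 2 fell, 0 rose and 4 did not pass (3 adjusted over the list alone, adjusted p = 0.429).

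The remaining lists that were fixed before the data were examined also did not pass in the bulks. For scent, amine and proline genes 4 rose, 2 fell and 6 did not pass (7 adjusted over the list alone, adjusted p = 0.429). Cytochrome P450 genes split into 5 up, 10 down and 14 not passing (17; adjusted p = 0.358), phenylpropanoid genes into 4, 9 and 10 (14; 0.257) and oxylipin genes, with OPR1 up by 1.36, into 3, 5 and 10 (8; 0.757), where the number before each adjusted p is the count adjusted over the list alone. In the same order, floral and meristem genes gave 4, 6 and 26 (10; 0.428), clock and flowering genes 6, 5 and 3 (12; 0.757), root genes 3, 6 and 10 (12; 0.453) and seed storage and starch genes 1, 2 and 11 (3; 0.757). Photosynthesis genes gave 1, 2 and 11 (3; 0.757), alcohol and aldehyde genes 3, 2 and 6 (5; 0.839) and ribosomal genes 3, 1 and 19 (4; 0.428), with RPL18 up by 1.09. The median, mean and test of the clock, scent, oxylipin and photosynthesis lists differed in sign. Camera tests a shift in 1 direction, so a list whose members change both ways can fail to pass. Only 3 of the 14 clock and flowering genes did not pass singly, against 12036 of all 17905 genes. A list of resistance genes had only 2 measured members and was not tested; Pi21 had log2 0.40 (adjusted p = 0.00154) and Pikm2 -1.22 (adjusted p = 0.0485), with a second probe set of Pikm2 not passing (log2 -1.80, adjusted p = 0.248).

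Of 7 further lists, chosen after the data were seen and tested as a family of their own, 5 passed in the bulks. Chlorophyll synthesis genes rose, 9 of 15 passing upward, 0 downward and 6 not passing (9 adjusted over the list alone, adjusted p = 1.15e-06). CHLD, a subunit of magnesium chelatase, had 5252 ± 60.2 against 2435 ± 133, and CPX rose by 0.61. JAZ repressors of jasmonate signalling rose (7 up, 1 down and 5 not passing, with 9 adjusted over the list alone, adjusted p = 0.0137), with JAZ11 at 785 ± 40.7 against 293 ± 39.0 and JAZ2 up by 3.19. Aquaporin genes fell (1 up, 10 down and 14 not passing, with 14 adjusted over the list alone, adjusted p = 0.0137), among them PIP2-4 by 1.73 and TIP1-1 by 0.96.

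Water stress genes also fell in the aromatic bulk (0 up, 5 down and 3 not passing, with 5 adjusted over the list alone, adjusted p = 0.0154). Among these, salT (log2 -1.2) and the dehydrin gene Dhn1 (log2 -1.04) fell, while weak further probe sets of Dhn1 gave 0.08 and 0.82 without passing. Phosphate genes fell (0 up, 6 down and 12 not passing, with 7 adjusted over the list alone, adjusted p = 0.0258), with the transporter gene PHT1-1 down by 0.85 and its other probe set not passing (log2 -0.33). With an estimated correlation these 5 lists kept adjusted p values from 0.000824 to 0.0357. The water stress call was lost among the brighter probe sets (adjusted p = 0.0647; over 13 alternatives from 0.0101) and the phosphate call with probe sets averaged (adjusted p = 0.0527; from 0.0173). Expansin genes gave 3 up, 9 down and 17 not passing (12; 0.227), and cell cycle genes 2, 1 and 37 (3; 0.584), with the counts in the order used above.

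**Figure D2:**
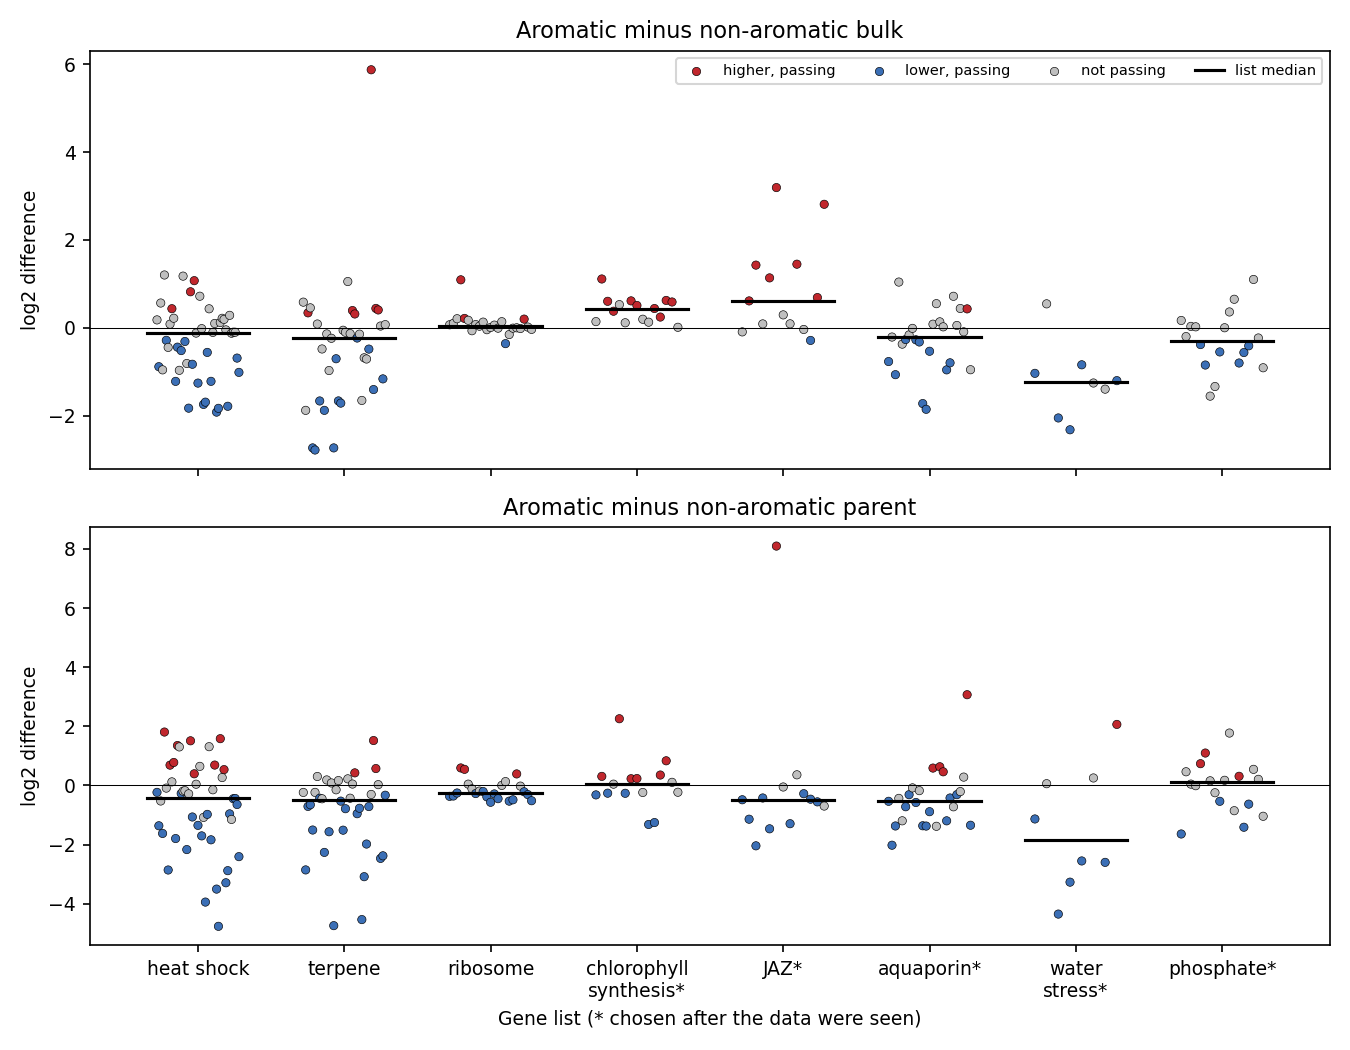
Log2 difference of each measured member of 8 gene lists between the bulks (upper panel) and between the parents (lower panel); points are genes, red for higher and blue for lower at an adjusted p under 0.05, grey otherwise, and the black line is the list median. Heat shock medians were -0.12 and -0.44, and the chlorophyll synthesis medians 0.44 and 0.05.

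The comparison of the parents asked how far the scented and the unscented variety differ in the same tissue. EIL1 (LOC4332697), a transcription factor of ethylene signalling, had 12700 ± 226 in the aromatic parent and 50.1 ± 10.2 in the non-aromatic parent (n = 4 each, log2 7.98, adjusted p = 1.34e-13). JAZ2 had 3933 ± 180 against 17.7 ± 13.8, and LOC4328727 had 28990 ± 888 against 43.2 ± 37.2. LOC4326061 rose by 7.81 and LOC9270995 by 5.75. In the other direction, LOC4327118 had 4.3 ± 2.16 against 9629 ± 541 (log2 -10.92, adjusted p = 5.27e-13). Against values this low the size of a difference depends on the pseudocount and is no measured fold. The flowering gene MADS56 fell by 7.39, BURP17 by 7.95, ASMT by 6.92 and ACO1, which makes ethylene, by 5.75. LOC4333210 fell by 8.97, but its 3 other probe sets had 1.28, 0.54 and 3.49, of which the first and the last passed. LOC4347994 fell by 7.25, with 1.75 for a weak second probe set that did not pass.

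Of 14 clock and flowering genes 5 rose, 2 fell and 7 did not pass between the parents, and the list did not pass. Those given here, CCA1, PCL1 and PRR1, were picked for a low adjusted p. CCA1 had 888 ± 72.7 in the aromatic and 11920 ± 1030 in the non-aromatic parent (log2 -3.74, adjusted p = 1.49e-12), while PCL1 and PRR1 rose by 6.27 and 1.99. The time of day of sampling was not part of the fit. A difference in it between groups cannot be told apart from 1 between varieties or lines. PCL1 had 1 aromatic parent array, replicate 4, at 2128 with the other 3 from 2646 to 2694, and a weak second probe set of CCA1 did not pass (log2 -0.50). The lipoxygenase genes LOX8 and LOX9 rose by 3.82 and 2.42, the aldehyde oxidase gene AO-1 by 2.57 and OsTUB6 by 3.14. As in the bulks, MADS14 (375 ± 22 against 4125 ± 112), MS and ICL were lower on the aromatic side, by -3.46, -4.0 and -2.99. For MS 1 array of the non-aromatic parent, replicate 3, lay at 225 with the others from 349.7 to 370.

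Between the parents 14777 of 57194 probe sets passed, 7134 higher and 7643 lower in the aromatic parent, and 6549 of them by at least 2-fold. Of 17905 genes 4015 rose, 4082 fell and 9808 did not pass. All 4 arrays of 1 parent lay above all 4 of the other in 9259 of the 17905 genes, called or not, against 2.86% by chance. In 90 genes with a known place in the gene order, 1 parent was below 50 and the other above 500. For 12 of these genes 18 further probe sets were bright, and 14 differed at least 4-fold the same way, but only 2 of 6 that were named from another sequence cluster did.

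Terpene genes were lower in the aromatic parent, with 20 of 36 falling, 3 rising and 13 not passing (24 adjusted over the list alone, adjusted p = 0.00502). PSY2 and PSY3, phytoene synthases of carotenoid synthesis, fell by 2.47 and 2.38, and the diterpenoid genes CYP76M7, KSL10 and CYP71Z6 by 4.74, 4.53 and 2.26. Heat shock genes were lower too (22 fell, 9 rose and 14 did not pass, with 35 adjusted over the list alone, adjusted p = 0.0165). HSP18.6 had 213 ± 25.8 against 5789 ± 350, and HSP24.1, hsp101 and HSP17.9A fell by 2.88, 2.41 and 1.84. Ribosomal genes fell by smaller amounts (14 fell, 3 rose and 6 did not pass, with 18 adjusted over the list alone, adjusted p = 0.0165). RPL7A-2 (1 non-aromatic array apart, at 10800) and RPS21 had log2 -0.57 and -0.53, though 1 further probe set of RPS21 did not pass (log2 -0.25), and RPL27 rose by 0.55. Each of these 3 lists had an adjusted p = 0.0333 with an estimated correlation, and the ribosomal call was lost with probe sets averaged (adjusted p = 0.0881; from 0.0156 over 13 alternatives).

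The other 13 tested lists did not pass between the parents. Scent, amine and proline genes gave 3 up, 5 down and 4 not passing, with 8 adjusted over the list alone (adjusted p = 0.42). In the same order and form, floral and meristem genes gave 3, 9 and 24 (12; 0.148, but 0.0361 among the brighter probe sets and up to 0.185 over 13 alternatives), clock and flowering genes 5, 2 and 7 (7; 0.691), cytochrome P450 genes 5, 8 and 16 (15; 0.719) and oxylipin genes 3, 5 and 10 (8; 0.842). Defence genes gave 3, 4 and 10 (8; 0.842), with Cht2 up by 1.79 and the protease inhibitor gene RBBI3.3 down by 2.48. A further probe set of Cht2 fell by 0.38 and another rose by 9.88. Phenylpropanoid genes gave 9, 6 and 8 (17; 0.842), with CAD2 up by 1.34 and PAL06 down by 2.06.

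For seed storage and starch genes the counts were 1, 3 and 10 (4; 0.691), with SSI down by 2.24, and for senescence genes 2, 2 and 2 (5; 0.719), with SGR down by 1.95. Root genes gave 4, 6 and 9 (10; 0.691), photosynthesis genes 3, 3 and 8 (6; 0.865), alcohol and aldehyde genes 5, 3 and 3 (9; 0.842) and WRKY genes 2, 3 and 1 (5; 0.842). The median, mean and test differed in sign for the alcohol and aldehyde, phenylpropanoid, photosynthesis, senescence and WRKY lists. Pi21 had log2 -0.65 (adjusted p = 1.06e-05) and Pikm2 -0.20 (adjusted p = 0.798).

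Of the lists chosen after the data were seen, JAZ genes fell in the aromatic parent (1 up, 9 down and 3 not passing, with 10 adjusted over the list alone, adjusted p = 0.0172). The call was lost with an estimated correlation (adjusted p = 0.0614; from 0.0145 over 13 alternatives), and JAZ2, at 8.10, pulled the mean to -0.03 against a median of -0.48. JAZ11 fell by 2.04. Aquaporin genes fell (4 up, 13 down and 8 not passing, with 18 adjusted over the list alone, adjusted p = 0.0172), a call also lost with an estimated correlation (adjusted p = 0.0739; from 0.0148). Lsi6, a silicon channel, fell by 2.02 and TIP4-1 rose by 3.07. The others did not pass: water stress genes gave 1, 5 and 2 (6; 0.406), with salT up by 2.07 (1 aromatic parent array apart, at 1144), and phosphate genes 3, 4 and 11 (8; 0.952), with median and mean of opposite sign. PHT1-1 rose by 1.1 in its brighter probe set and fell by 2.11 in the other. Chlorophyll synthesis genes gave 6, 5 and 4 (12; 0.952), expansin genes 3, 8 and 18 (12; 0.493) and cell cycle genes 5, 8 and 27 (13; 0.493).

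Genes that separated the bulks were compared with those that separated the parents, 2 comparisons that share no arrays but take their residual spread from the same fit. MS, MADS14, ICL, LOC4347994 and BADH2 were lower and JAZ2, OsTUB6 and LOC9270995 higher on the aromatic side of both. Of 3837 genes called in both comparisons, 2937 had the same direction and 900 opposite directions, against 1327 expected from independent lists in either case. Among probe sets 4694 had the same direction (1372 expected) and 1698 the opposite (1375 expected). The expected counts leave out that probe sets with little spread pass more readily in both comparisons. Across all 17905 genes, which are not independent replicates, the log2 differences had r = 0.269 and rho = 0.285.

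**Figure D3:**
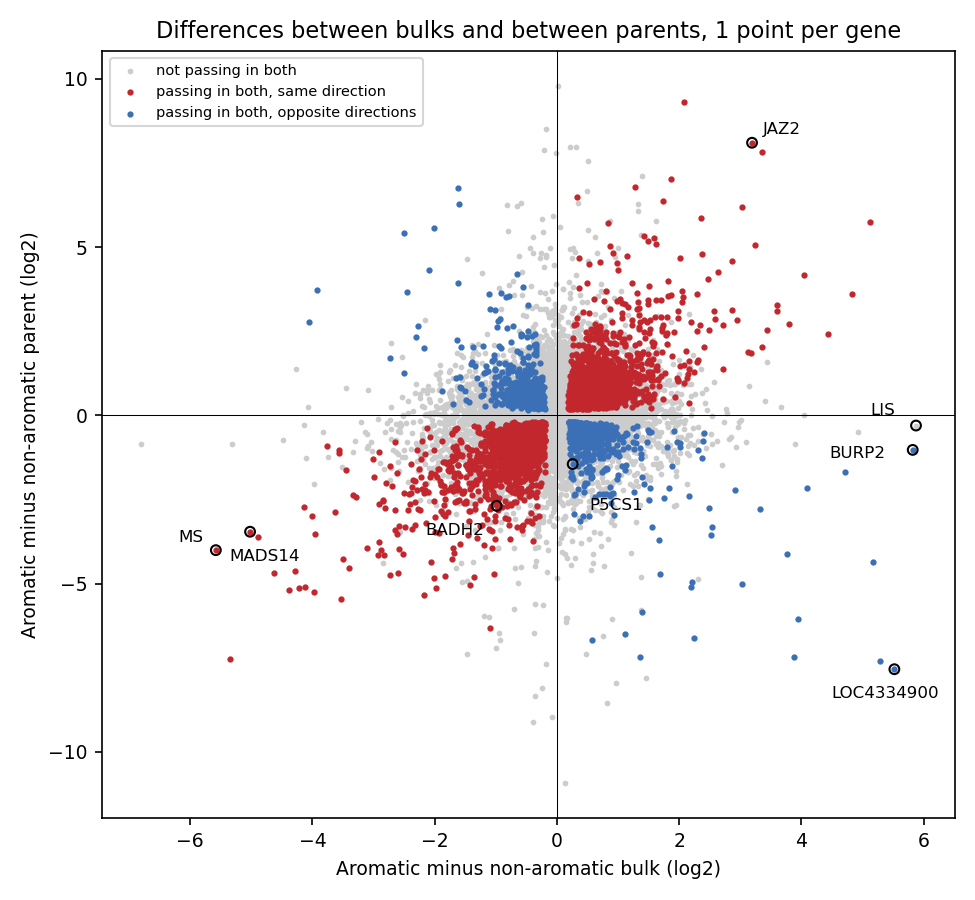
Log2 difference between the aromatic and non-aromatic bulk (x axis) and between the aromatic and non-aromatic parent (y axis), 1 point per gene; red points passed in both with the same direction, blue points passed in both with opposite directions, grey points did not pass in both. The 2937 red genes outnumber the 900 blue ones, and BADH2 lies at -0.99 and -2.69.

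The test of the difference itself asked where the parental contrast departed from that of the bulks. LOC4334900 rose by 5.52 in the bulks and fell by 7.54 in the parents, with 1642 ± 163 and 48.2 ± 38.8 in the aromatic and non-aromatic bulk against 34.9 ± 20.2 and 5437 ± 390 in the parents. LOC4348034 had a parental difference lower by -12.57 (adjusted p = 2.93e-07), though 1 non-aromatic bulk array lay at 28.5 and the others at or below 2.43. Its other probe set gave -4.80, with no call in the bulks (log2 0.16, adjusted p = 0.911). LIS and BURP2, both higher in the aromatic bulk, had parental differences of -0.30 and -1.03, lower by -6.18 and -6.85. EIL1, at 6549 ± 527 and 5249 ± 391 in the bulks, and LOC4328727, at 23270 ± 564 and 22970 ± 224, differed by 7.66 and 9.78, and MADS56, BURP17 and LOC4327118 by -7.21, -8.92 and -11.05. PCL1 and JAZ2 had parental differences higher by 4.95 and 4.91, and P5CS1 had -1.70 (adjusted p = 1.39e-08). In all, 11081 probe sets passed (5259 with a higher and 5822 with a lower parental difference), 5550 of them by at least 2-fold.

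The mean of the bulks was also set against the mean of the parents, with 1 aromatic and 1 non-aromatic group on each side. A gene can still pass through 1 group alone. LOC4340998 (2534 ± 95.5 and 2109 ± 66.4 in the bulks, 9.31 ± 7.36 and 14.4 ± 19.0 in the parents) and LOC4340976, both on chromosome 6, were higher in the bulks by 7.98 and 7.95. For LOC4340998 a second probe set did not differ past the threshold (log2 -0.52), and 1 array of the non-aromatic parent lay at 42.9 with the others at or below 5.43. For LOC4340976, LAC4 and BC1 1 array of a group also lay apart from the rest. LOC4350773 on chromosome 11 rose by 6.70, the kinase gene OsWNK7 by 3.55, the protease gene FTSH6 by 2.84 and RBBI3.3 by 2.34. The laccase genes LAC7 and LAC4 were lower in the bulks by -2.93 and -3.35, and the secondary wall genes CESA7 and BC1 (LOC4333114) by -1.94 and -2.19. LOC4350947 had -4.40, BADH2 -0.76 (adjusted p = 9.09e-06) and TIP4-1 -2.34, although a weak second probe set of TIP4-1 did not pass (log2 -0.37). For BADH2 the aromatic bulk (326 to 417) and aromatic parent (288 to 410) overlapped, so its difference came from the non-aromatic side. For TIP4-1 it came mainly from the aromatic parent, at 14734 to 15649 with all other arrays at or below 1873. Here 13733 probe sets passed, 6703 higher and 7030 lower in the bulks, and 3558 by at least 2-fold.

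Called genes were counted by chromosome, because lines chosen for scent could differ most where the trait maps. On chromosome 8, which carries BADH2, 388 of 1206 genes passed in the bulks (32.2%, against 32.8% elsewhere) and 566 of 1206 in the parents (46.9% against 45.1%). Fisher's exact test called 0 of 12 chromosomes in either comparison after adjustment; at an unadjusted p under 0.05 it gave 0 in the bulks and 2 in the parents. With at least 2-fold differences, 5 chromosomes passed in the parents. Chromosome 12 had the highest share then, 21.1% against 15.4% elsewhere (adjusted p = 6.2e-05), and chromosome 2 the lowest, 12.5% against 16.2%.

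Around BADH2, 15 of the 52 measured genes among the 50 on either side passed in the bulks (28.8%, against 32.8% elsewhere, exact p = 0.658). In the parents 25 of 52 did (48.1% against 45.2%, exact p = 0.679). LOC4345562, at the edge of this stretch, was lower on the aromatic side of both comparisons, by -2.87 and -4.0. It was named after its values had been seen.

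**Figure D4:**
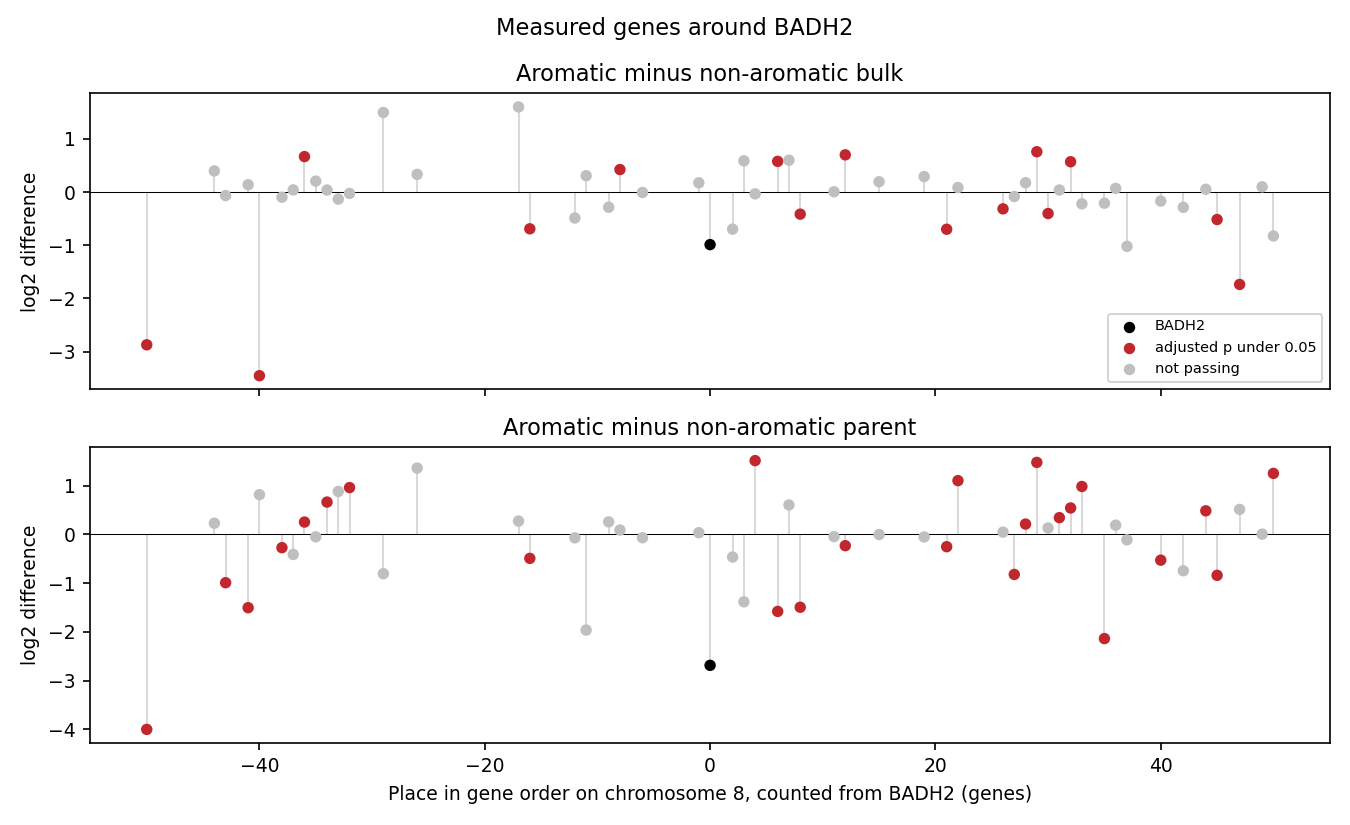
Log2 difference of the measured genes up to 50 genes either side of BADH2, by place in the gene order of chromosome 8, between the bulks (upper panel) and between the parents (lower panel); red points passed an adjusted p under 0.05, grey points did not, and BADH2 is black. Of the 52 neighbours, 15 passed in the bulks and 25 in the parents.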

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

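The tests of explanations for BADH2 and for genes dark in 1 parent were chosen after the result was seen, while the search for arrays apart from their group and the test of the parental against the bulk difference were set before the data were examined.

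Of 258 gene and group pairs, 12 (4.65%) had 1 array far from the other 3, where chance gives about 1 in 20. The value is the gap to the nearest array as a share of the group's range on the log2 scale. In the non-aromatic bulk these were ADC1 (0.878), LOC4340976 (0.972), LOC4348034 (0.928), LOC9270995 (0.862) and PCL1 (0.914). In the aromatic parent they were LAC4 (0.865), PCL1 (0.925) and salT (0.86). In the non-aromatic parent they were BC1 (0.872), LOC4340998 (0.881), MS (0.887) and RPL7A-2 (0.861). Replicate 4 was the array apart in 7 of the 12, from 3 groups, and whether that replicate stands apart was not tested.

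The parental difference departed from that of the bulks in 59 of 77 genes tested for it in limma, with adjusted p from 1.75e-11 to 0.0445. These genes were chosen mostly for large changes, in part in this contrast, and over all genes 6041 of 17905 (33.7%) passed. The values are the parental minus the bulk log2 difference. In 9 genes both comparisons passed in opposite directions: LOC4334900 (-13.06), LOC4348034 (-12.57), BURP2 (-6.85), JAZ11 (-3.47), P5CS1 (-1.70), PHT1-1 (1.95), Cht2 (2.82), salT (3.27) and LOX8 (4.37). For PHT1-1 and Cht2 a second probe set gave the parents the opposite sign. Opposite directions do not hold on other probe sets of LOC4348034 (0.16), Cht2 (-0.40) and PHT1-1 (-0.33), which did not pass in the bulks. For P5CS1 the bulk call was lost when only the bulks were fitted (adjusted p = 0.078, against 2.17e-05 at the lowest of 17 alternatives).

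In 15 genes the direction was shared and the parental difference was larger. These were CCA1 (-3.34), HSP18.6 (-2.93), BADH2 (-1.70), SSI (-1.65), hsp101 (-1.39), PSY3 (-1.21), HSP24.1 (-1.09), SGR (-0.77), HSP17.9A (-0.62), RPL27 (0.33), PRR1 (1.21), AO-1 (2.02), TIP4-1 (2.64), LOC4326061 (4.46) and JAZ2 (4.91). Other probe sets of CCA1 (0.065), HSP18.6 (0.24), RPL27 (-0.28) and TIP4-1 (-0.02) did not pass in the bulks. In 9 the direction was shared and the bulks differed more: LOC4326149 (-1.23), CHLD (-0.80), PRR37 (-0.66), RPL18 (-0.50), CPX (-0.38), WRKY76 (0.76), CYP99A3 (1.19), CPS2 (1.23) and MADS14 (1.56).

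In 19 genes only the parents passed: LOC4327118 (-11.05), BURP17 (-8.92), LOC4333210 (-8.89), MADS56 (-7.21), ASMT (-5.92), ACO1 (-5.04), KSL10 (-2.88), RBBI3.3 (-2.73), PSY2 (-2.51), Lsi6 (-1.81), BADH1 (-1.01), OAT (-0.83), RPL7A-2 (-0.57), RPS21 (-0.37), CAD2 (1.45), LOX9 (2.46), PCL1 (4.95), EIL1 (7.66) and LOC4328727 (9.78). In 7 only the bulks passed: LIS (-6.18), MADS50 (-2.25), Cht-1 (1.73), CPS4 (2.55), Hd3a (2.96), NAS2 (3.32) and LOC4337008 (5.95). Other probe sets did not pass in the difference for CCA1 (-0.57), LOC4326061 (1.93), LOX9 (2.64), PHT1-1 (-1.78), RPS21 (-1.40 and -0.29) and TIP4-1 (2.26). For PRR37 a bright second probe set had a larger difference in the parents (0.92, adjusted p = 0.00144) and no call in the bulks (0.15). For LOC4333210 others gave 0.58 and 0.25, not passing, and 4.27, passing in the opposite direction. In the bulks themselves, other probe sets of LOC4333210 (-0.78) and LOC4328727 (0.53 and 0.68) did pass, so for these genes the grouping depends on the probe set. A dimmer probe set of each passed in the parents alone, as the brightest did. It had 0.70 in the bulks and 1.28 in the parents for LOC4333210, and 0.99 and 5.80 for LOC4328727.

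On linear intensity, BADH2 in the non-aromatic bulk lay 20.4% of the way from the aromatic to the non-aromatic parent, and in the aromatic bulk 1.12%. All shares between the parents given here are linear, and on the log2 scale this bulk would lie further from the aromatic parent. A single mislabelled array is argued against, because all 4 arrays of the bulk lay between 17.8% and 24.4%. Lines of the non-aromatic bulk could carry the aromatic parent's segment around BADH2: 7 genes within 150 genes of it that differed at least 4-fold between the parents had a median aromatic share of 77.9%, and 6 of them were over 50%. As 7.74% of 594 stretches elsewhere, which overlap one another, were as high, this share cannot be told apart from chance with so few genes. The lines of this bulk were chosen as unscented, which goes against most of them carrying a non-functional BADH2. Their alleles at BADH2 are not given. Regulation of BADH2 that differs between the lines and the parents stays open and was not tested.

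In 90 genes 1 parent was below 50 and the other above 500, 48 of them bright in the aromatic parent. A mixture of the alleles of both parents may underlie the bulks. Scaled between the parents on linear intensity, the aromatic bulk had a median of 62.7% of the aromatic parent's level (quartiles 32.1 and 88.7). The non-aromatic bulk had 44.8% (16.9 and 86.3). Only 58 and 56 of the 90 genes lay between 10 and 90%, the rest near or beyond a parental level, and a median over genes at both ends decides little, so this stays open. Sequence differences under the probes of a single probe set would leave other probe sets alike. Yet 77.8% of 18 other probe sets, from 12 genes, differed at least 4-fold the same way. The exact 95% interval of 52.4 to 93.6 takes the 18 as independent and is likely too narrow. Sequence differences stay open all the same, because only 2 of the 6 probe sets named from another sequence cluster differed so and the others may share sequence. That condition was added after the share was seen. Presence or absence of the genes in the parental genomes was not tested.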

How the results depend on the processing

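The alternatives for the lists added later were chosen after the data were seen, and the others before.

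Of 2309 repeats of 122 named gene results under all alternatives, 2270 kept direction and side of the threshold, 23 lost the call and 16 reversed. No result moved with a trended prior, array weights or a pseudocount of 16 among these genes. Nor did any with quantile normalization or median centring, at 122 repeats each. Both could change almost nothing, since the arrays already had the same median and upper quartile. Same-numbered arrays of different groups had residual correlations from -0.00709 to 0.0136, with a median of 0.00225 against -0.000859 for other numbers. These are small, but 9 of the 16 arrays correlated best with an array of their own number. A weak pairing by replicate number is therefore not excluded. With a replicate block the counts were 9636, 14040, 10147 and 12927 for the bulks, the parents, their difference and the bulks against the parents. The odds ratio of BADH2 neighbours in the bulks then went to 1.08.

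A 2-fold minimum left 3417, 6549, 5550 and 3558 probe sets and 1037 shared ones, as it must remove small changes, and called 5 chromosomes in the parents. Among the brighter probe sets 2 lists passed in the bulks (defence beside heat shock, adjusted p = 0.0443), 4 in the parents (floral and meristem genes added, 0.0361) and 1 chromosome in the parents, and the neighbours' odds ratio in the bulks was 1.02. An estimated correlation left 0 added lists in the parents. Fry, which tests a list on its own genes alone, called 15 lists in the bulks, 12 in the parents and 6 added ones in the parents, with reversed parental directions (p values) for clock (0.373), defence (0.21), WRKY (0.774), chlorophyll synthesis (0.0031) and phosphate genes (0.388). With probe sets averaged 2 lists passed in the bulks (terpene added, adjusted p = 0.0419) and 2 in the parents (ribosomal call lost, 0.0881), and photosynthesis in the bulks (0.971) and chlorophyll synthesis (0.917) and phosphate (0.878) in the parents reversed. Neighbourhoods of 25 and 100 genes gave parental odds ratios of 0.652 and 0.912. Except where the construction is named, the cause was not tested.

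Other probe sets of the same gene reversed HSP18.6 (0.24) and Dhn1 (0.080, 0.82) in the bulks, P5CS2 (1.84, 0.052), LOC4333210 (1.28, 0.54, 3.49), LOC4347994 (1.75), Cht2 (-0.38) and PHT1-1 (-2.11) in the parents, and LOC4340998 (-0.52) between bulks and parents; the cause was not tested.

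Leaving out 1 replicate at a time gave 9229 to 9626 probe sets in the bulks, 13499 to 13776 in the parents, 10204 to 10584 for the difference, 12777 to 13308 for bulks against parents and 4184 to 4493 shared. List and chromosome counts stayed as reported. The neighbours' odds ratio ranged from 0.893 to 1.12 in the bulks and 0.941 to 1.11 in the parents, P5CS2 in the bulks from -0.085 to 0.073, and the parental p of chlorophyll synthesis from 0.868 to 0.986 and of phosphate genes from 0.856 to 1, all on either side of no difference and none passing. Low signal limits the rest: the median residual SD was 1.09 in the dimmer and 0.196 in the brighter probe sets.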

Other observations

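The tests of genes bright in both bulks and the neighbourhood splits were chosen after the result was seen.

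LOC4340976, LOC4340998 and LOC9270148 on chromosome 6 and LOC4350773, LOC4350802 and LOC4350668 on chromosome 11 were above 200 in both bulks and below 50 in both parents. LOC4339148 and LOC4343779, on chromosomes 5 and 7, complete the 8 genes with a known place; those not among the named genes were listed after their values were seen. Among all probe sets 43 had this pattern and 2 its mirror, a count first meant as a test of growth stage and then not used as one, since stage could act in 1 direction. Growth stage or field conditions acting on genes scattered over the genome are argued against for these 8 genes alone. Of them 5 lay within 50 genes of another (permutation p = 1e-04, the smallest that 10000 draws can give). Stage or conditions that act on neighbouring genes together are not excluded by this. Segments in the pooled lines that the sampled parents do not carry are a candidate explanation. It rests on the same count (62.5% of the genes, against a median of 0 in random gene sets), which is not a second test. Tandem copies that respond together were not tested, and the genes are few.

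If the arrays of 1 group shared 1 RNA pool, stress and defence genes, which vary between plants, should vary no more than other genes of the same level. The median ratio of their spread to that of 200 matched genes was 1.03 over 89 genes (quartiles 0.864 and 1.33; 13 genes at 1.5 or more). A shared RNA pool may therefore explain how close the arrays lie, but plants grown alike could vary as little, which was not tested.

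Other splits of the arrays into groups of the same sizes were compared with the real one. They exclude only chance in the spread between these arrays, which may be technical, and not chance between plants, pools or lines. In this sense chance is excluded for the bulks (10634 probe sets, highest other 9, 1 of 35 splits as large) and the parents (14777, other 6, 1 of 35). The same holds for their difference (11081, other 676, 1 of 100) and bulks against parents (13733, other 615, 1 of 100). The shared direction gave 4694 (other 1, 1 of 100), but other splits of the bulks and of the parents called at most 9 and 6 probe sets. Hardly any could then be shared, so this count cannot decide whether the directions agree beyond chance. For the list counts the real split was also the largest in the bulks (1, other 0, 1 of 35 splits) and parents (3, other 2, 1 of 35). The margin was 1 list each, and 1 of 35 is the smallest share that these splits can give. Chance is therefore not firmly excluded for the list counts. The added lists of the bulks gave 5, with 4 as the highest other (1 of 35 splits as large), but they were chosen after the data were seen, so this does not exclude chance. It is not excluded for the added lists of the parents either (2, other 2; 6 of 35 splits). For chromosomes and for the neighbours of BADH2, in bulks and parents alike, 35 of 35 splits gave as much, because 0 passed in any. The neighbour result was first measured as -log10 p (0.182 and 0.168, highest other 0, 1 of 35); since other splits call too few genes for that test, the measure was changed to passed or not after this was seen.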
